A study of Mus musculus with 7 samples.

How the data were processed

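The data were RNA-seq values of 7 libraries from mouse epithelium labelled as colorectal, 3 from wild-type mice (Ctrl) and 4 from mice with Stk24 (MST3) knocked out in intestinal epithelial cells (cKO). Per the labels, RNA was extracted with Trizol from mice of 8 weeks. The design text speaks of littermates, and no label says that each library came from a separate mouse, so p-values measure the spread between these libraries. The same text names a treatment with a carcinogen and a colitis-inducing agent, whereas the treatment label of each sample states that no drug was given; both groups carry the same label, and the conflict was left open.

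The deposited table gave 1 FPKM value per gene and library, for 46671 genes with their symbols, gene lengths and coordinates. Per the submitters' processing notes the reads were aligned with HISAT2; its version, the counting program, its strand setting and the annotation release are not given in the sources used here. The chromosome sequences named in the table are those of the GRCm39 build, and coordinates are printed as the table gives them. FPKM times gene length was a whole multiple of 1 step per library in 100% of the deposited values, within 0.01 of a whole number, so the number of reads behind each value could be recovered. The libraries held between 14659708 and 19659622 such reads. The library sizes by which the deposited FPKM had been divided were not the totals but were proportional to median-of-ratios size factors of the 7 libraries, and lay between 0.891 and 1.10 times the totals. With such size factors, comparisons rest on the assumption that most genes did not change. FPKM sums also differed between libraries. Libraries differed by more than sampling noise, with a chi-square per degree of freedom of at least 23.6 in every pair, so that none was a repeat sequencing of another. This does not settle whether any pair came from the same mouse. By this measure the closest pairs were cKO replicates 1 and 2, at 23.6, and cKO replicates 3 and 4, at 31.7. The least similar pair was cKO replicates 1 and 4, at 89.1. By Spearman correlation over genes the least similar pair was Ctrl replicate 3 and cKO replicate 3, at 0.943.

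Genes with a mean of at least 0.5 FPKM were tested, 13057 in all. Values were put on the scale log2(FPKM + 0.5), which understates the change of genes of low level, and the groups were compared with limma (version 3.58.1, in R 4.3.3), using lmFit and eBayes with a trend, 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. No covariate was used. For single values an exact permutation test over the 35 splits of the libraries into 3 and 4 was run, whose smallest 2-sided p is 0.0571. Gene lists were compared with camera from limma, with a preset correlation between genes of 0.01 and adjustment over the 49 of 62 lists that had at least 5 tested members. Of 1126 listed symbols, 2 were not matched in the table. Alternatives were camera with an estimated correlation, camera on ranks and fry. The lists of pathways and cell types, the tests and the rule for naming genes were fixed before the data were examined. Libraries were simulated with the means of the real genes and a bounded estimate of their spread within groups, each gene drawn independently. On these, limma called 46 of 96 genes changed by 1 log2 unit (47.9%), 68 of 93 changed by 2 log2 units (73.1%), and 5 of 12772 unchanged genes, among 13020 simulated genes tested. In the same simulation, camera called the 1 list that had been raised by 0.5 log2 units and none of the others among 49. Structure shared between genes of a library was absent from this simulation. It therefore does not give the error rate in the real libraries, where another split of the libraries gave up to 12 called genes.

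The genes named were Stk24, Pgam5, Yap1, Wwtr1, Stk25 and Stk26; among genes past the threshold with a mean of at least 1 FPKM, a symbol that is not a predicted name and libraries that do not overlap between the groups, up to 12 in each direction by size of change, filled up to 12 by the smallest p under the same conditions; in each list that passed, and in the YAP/TEAD list, the 4 members with the smallest p; and for a cell type list that passed, also its most abundant member. Marker genes of tissue regions outside these parts were chosen after their values were seen.

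Alternatives fixed before the data were examined were pseudocounts of 0.1 and 1, no filter and a mean of at least 1 FPKM, a second median-of-ratios rescaling over tested genes, rescaling to a common sum (TPM), quantile normalization, rescaling on a sum without immunoglobulin genes, mitochondrial genes and the 20 most abundant genes, robust and untrended variance, array weights, the replicate number as a block, other thresholds, and leaving out each library in turn. Added after seeing the data were FPKM per recovered read, limma voom on the recovered reads with at least 10 reads in 3 libraries, protein-coding genes only, and removal of each library's trend with gene length or with the GC content of the longest transcript of the gene (GENCODE M21, matched by symbol for 93.5% of tested genes). Trends were fitted by lowess with a span of 0.3. Figures and tables were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9. A floor of 3 reads was used where a group had none, and such bounds cover counting error only.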

Results

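RNA was sequenced from intestinal epithelium of 8-week-old mice. The samples are labelled as large bowel, although their regional markers were those of small intestine. The protein kinase MST3, encoded by Stk24, had been knocked out in the intestinal epithelium of 4 samples (cKO), and 3 wild-type samples (Ctrl) served as the control. MST3 is a kinase of the STE20 family, and the title of the series places it between the mitochondrial phosphatase PGAM5 and the transcriptional co-activator YAP in cancer progression. The 7 libraries held between 14659708 and 19659622 reads assigned to genes. A gene 1 kb long that gave 3 reads stood at between 0.155 and 0.216 FPKM, which sets the level below which values were mostly counting error. The mice carried no drug treatment according to the treatment labels, whereas the description of the design names a carcinogen and colitis protocol, so the state of the tissue is known only as far as these labels go.

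The first question was whether the targeted gene was lower in the samples labelled as knockouts. Stk24 fell in cKO, from 19.9 ± 0.926 FPKM in Ctrl (SD, n = 3) to 3.34 ± 0.435 FPKM in cKO (SD, n = 4). The difference was -2.42 on the log2 scale (SE 0.12, limma adjusted p = 0.00043), and 16.7% of the Ctrl mean was left. Stk24 lies on chromosome 14 from 121521599 to 121618269 on the minus strand of GRCm39. It was read between 2455 and 2827 times in each Ctrl library and between 370 and 421 times in each cKO library, so the libraries of the groups did not overlap. The exact 2-sided permutation test gave p = 0.0571, the smallest value that 3 against 4 libraries allow.

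Of the other genes named by the study's axis or closest to Stk24, 3 could be tested in limma, and no difference was called for them. Pgam5, a phosphatase of the mitochondrial membrane, stood at 10.99 ± 0.747 FPKM in Ctrl (SD, n = 3) and 11.8 ± 2.21 FPKM in cKO (SD, n = 4). Yap1, which encodes YAP, stood at 16.5 ± 1.499 and 16.2 ± 0.879 FPKM, a log2 difference of -0.030 (SE 0.11) that turned to 0.056 after rescaling to TPM. Stk25, a kinase closely related to Stk24, stood at 55.8 ± 16.2 and 47.8 ± 6.25 FPKM. None of these 3 genes passed the test, with limma adjusted p of 0.902 for Pgam5, 0.949 for Yap1 and 0.794 for Stk25. Wwtr1, which encodes the YAP paralog TAZ, and Stk26 lay below the level required for testing. Wwtr1 stood between 0.0215 and 0.112 FPKM in Ctrl and between 0.0941 and 0.331 FPKM in cKO (exact 2-sided permutation p = 0.114). Stk26 stood between 0.472 and 0.612 FPKM in Ctrl and between 0.253 and 0.621 FPKM in cKO (exact p = 0.286). For both, the exact test could not have called a difference, since its smallest p here is 0.0571.

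**Figure D1:**
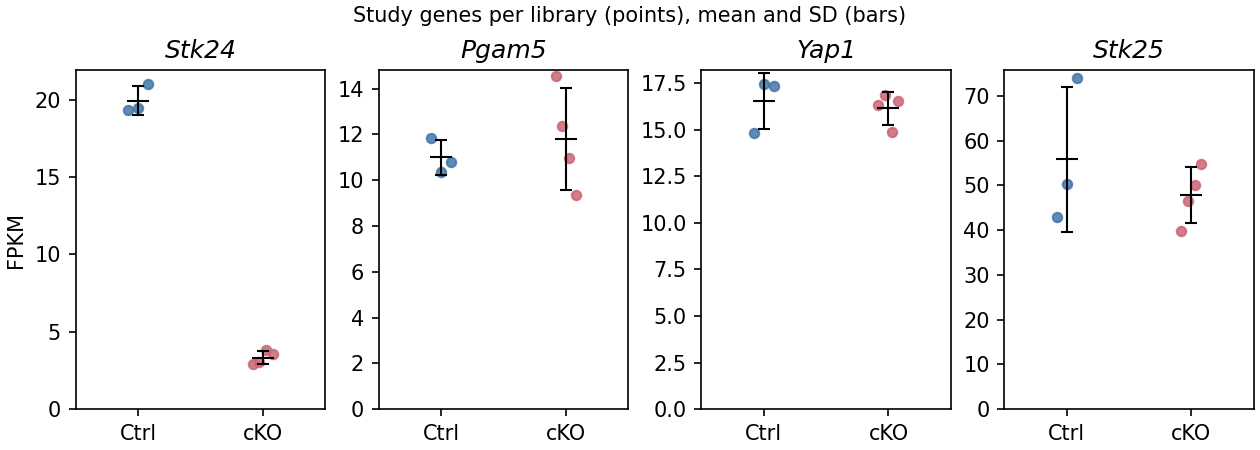
FPKM of Stk24, Pgam5, Yap1 and Stk25 in each library on linear axes that start at 0, with 3 Ctrl and 4 cKO libraries as points and the mean and SD as bars. Stk24 averaged 19.9 FPKM in Ctrl and 3.34 FPKM in cKO without overlap, whereas the libraries of both groups overlapped for the other genes.

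Beyond Stk24, few genes separated the genotypes. Of 13057 genes tested, 4 passed an adjusted p of 0.05 in limma, and all 4 fell in cKO: Stk24, Gm10499, Gm5425 and Mir7052. The last 3 lie outside the naming rule fixed beforehand and were chosen after their values were seen. Gm10499, a gene among the nonclassical major histocompatibility complex (MHC) class I genes on chromosome 17, fell from 66.03 ± 12.8 FPKM (SD, n = 3) to 22.5 ± 3.25 FPKM (SD, n = 4), a log2 difference of -1.53 (SE 0.17, adjusted p = 0.048). The pseudogene Gm5425 on chromosome 10 fell from 5.01 ± 0.310 to 2.15 ± 0.0625 FPKM, a log2 difference of -1.05 (SE 0.11, adjusted p = 0.040). Mir7052 rested on 8 reads in the 3 Ctrl libraries together and on 0 reads in cKO, at least 3.21-fold lower against a floor of 3 reads over the cKO group, and it lies inside the gene Josd2 on the same strand. Gm10499 overlaps Gm8909 and has near-identical relatives, so the division of its reads among them is uncertain, and a pseudogene such as Gm5425 can likewise share reads with the gene it derives from.

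At an unadjusted p under 0.05 there were 1171 genes, 553 higher and 618 lower in cKO. Libraries of the groups did not overlap for 1323 genes, or 10.1% of those tested, where chance gives 5.71%. Neither count stands out from regrouped libraries, since 6 of the 35 splits of the 7 libraries into 3 and 4, the real one included, gave at least 1171 genes at that p (highest 1974), and 5 gave at least 1323 genes without overlap (highest 1838). The count of 1171 also depended on the processing. It was 658 after removal of each library's trend with GC content and 1014 after removal of the length trend, but 1702 with array weights. Leaving out any 1 library ended the calls of Gm10499 and Gm5425, and all but the omission of cKO replicate 1 ended that of Mir7052. The log2 differences then stayed between -1.65 and -1.38 for Gm10499 and between -1.10 and -1.02 for Gm5425. The count of called genes then lay between 1 and 7, highest without cKO replicate 1.

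The lower genes that came next in the order of p and whose libraries did not overlap were led by H2-T23, which encodes the nonclassical class I molecule Qa-1. H2-T23 stood at 368 ± 45.7 FPKM in Ctrl (SD, n = 3) and 150 ± 24.9 FPKM in cKO (SD, n = 4), with a log2 difference of -1.30 (SE 0.17) and a limma adjusted p of 0.148. That adjusted p was 0.041 after rescaling to TPM, 0.030 after quantile normalization and 0.018 when the values were expressed per recovered read. H2-T23 passed under no other alternative, and its adjusted p lay between 0.161 and 0.620 when 1 library was left out. Next to it on chromosome 17, H2-T22 stood at 24.2 ± 4.33 and 10.8 ± 1.68 FPKM. Rpl21, a protein of the large ribosomal subunit, stood at 52.6 ± 7.27 and 24.3 ± 3.79 FPKM. The log2 differences of the others that filled the list were -0.69 for Phf1, a Polycomb-associated protein, -0.82 for the phosphatase gene Ppm1j, -0.73 for Tmem160, -0.69 for Hyi, -0.80 for the complex I subunit Ndufs6, -1.09 for the peroxisomal thiolase Acaa1b and -0.87 for the mitochondrial protein gene Romo1. Mir7051, inside Etfb, was read 11 times in Ctrl and 0 times in cKO, at least 4.41-fold lower against the same floor. None of these passed the test in limma, with adjusted p between 0.148 for H2-T23 and 0.388 for Romo1, although Mir7051 passed without Ctrl replicate 1 (adjusted p = 0.0085).

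On the higher side no gene passed, and the genes named here had adjusted p between 0.367 for Snord16a and 0.452 for Suz12 in limma. Kitl, the ligand of the receptor Kit, stood at 8.38 ± 0.656 FPKM in Ctrl (SD, n = 3) and 12.4 ± 0.980 FPKM in cKO (SD, n = 4). The deubiquitinase gene Usp34 stood at 4.77 ± 0.0339 and 7.23 ± 0.585 FPKM, and the transcription factor gene Klf7 at 1.06 ± 0.134 and 2.06 ± 0.160 FPKM. The log2 differences of 5 further genes were 0.49 for Cdc27, 0.54 for Rasa1, 0.41 for Sp3, 0.60 for Pgap1 and 0.39 for Suz12, a subunit of Polycomb repressive complex 2. H2-T10, a class I pseudogene, stood at 1.29 ± 0.375 and 2.86 ± 0.380 FPKM. Snord16a, inside Rpl4, had 1 read in the Ctrl libraries together and 19 reads in cKO, and Ighg2b, an immunoglobulin constant region, stood at 0.478 ± 0.560 and 4.82 ± 3.43 FPKM.

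Among gene lists fixed beforehand, those of oxidative phosphorylation, ribosomal proteins, fatty acid oxidation, MHC class I presentation, and T cells and innate lymphoid cells were lower in cKO, and that of immunoglobulin genes was higher. Of 49 lists with at least 5 tested genes, 6 passed an adjusted p of 0.05 in camera with a preset correlation of 0.01, 5 lower and 1 higher. None of the 6 calls held with a correlation estimated from the libraries, where each of the 6 had an adjusted p of 0.958.

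Nuclear-encoded oxidative phosphorylation genes, which encode the subunits of the respiratory chain and ATP synthase, were lower in cKO in 53 of 61 tested members, with a median log2 difference of -0.19 (camera adjusted p = 2.45e-07, and adjusted p = 0.958 with an estimated correlation). Over all genes tested, 0 members passed in limma, and 5 passed when adjusted over the list alone, with 14 at an unadjusted p under 0.05. Ndufa2, a subunit of complex I, stood at 147 ± 21.8 FPKM in Ctrl (SD, n = 3) and 75.6 ± 17.9 FPKM in cKO (SD, n = 4). Ndufa3 stood at 187 ± 9.98 and 112 ± 18.9 FPKM, and Ndufs6 at 118 ± 10.95 and 68.0 ± 9.71 FPKM. Cox5b, a subunit of cytochrome c oxidase, stood at 401 ± 38.3 and 237 ± 43.9 FPKM. The mean of the list was 0.25 lower in cKO on the log2 scale (SE 0.12, exact 2-sided permutation p = 0.114). These genes are short, with a median length of 949 bases against 3138 bases over all genes tested, and after removal of each library's trend with gene length the median difference was -0.055 with an adjusted p of 0.040. The size of the difference also depended on single libraries and on scaling, with a median of -0.12 without Ctrl replicate 1, -0.29 without Ctrl replicate 3 and with array weights, -0.078 after quantile normalization, -0.104 with TPM and -0.095 with the sum that left out abundant genes. Reads of mitochondrially encoded genes made up 3.71% to 7.51% of a library and were highest in cKO replicates 3 and 4. The list of these genes had 14 of 15 members higher in cKO, with a median log2 difference of 0.38, and did not pass (adjusted p = 0.068, and adjusted p = 0.958 with an estimated correlation). Its adjusted p at the preset correlation depended on the setting, from 0.00029 without cKO replicate 1, 0.0062 without Ctrl replicate 2, 0.0096 after removal of the length trend and 0.012 without cKO replicate 2 to 0.578 without Ctrl replicate 1 and 0.828 with array weights. It also passed with FPKM per recovered read (0.021), voom (0.026), camera on ranks (0.028), quantile normalization (0.035) and no variance trend (0.043).

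Ribosomal protein genes were lower in 66 of 83 members, with a median log2 difference of -0.20 (camera adjusted p = 0.00026, and adjusted p = 0.958 with an estimated correlation). Of these, 0 passed in limma over all genes and 1, Rpl21, passed when adjusted over the list alone. Rpl38 stood at 229 ± 32.8 FPKM in Ctrl (SD, n = 3) and 138 ± 44.0 FPKM in cKO (SD, n = 4), Rps28 at 280 ± 105 and 138 ± 56.1 FPKM, and Rps27a at 156 ± 36.5 and 97.5 ± 18.3 FPKM. The call was lost, and the median came closer to 0, without Ctrl replicate 1 (-0.078, adjusted p = 0.316), after quantile normalization (-0.090, adjusted p = 0.075), with array weights (-0.066, adjusted p = 0.108) and after removal of the length trend (-0.066, adjusted p = 0.482). The median was also smaller, at -0.12 without cKO replicate 3, -0.108 with TPM and -0.099 with the sum that left out abundant genes. Many ribosomal protein genes have processed pseudogenes that can share their reads.

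Genes of fatty acid oxidation and targets of the lipid-sensing receptor PPAR were lower in 20 of 24 members, with a median log2 difference of -0.17 (camera adjusted p = 0.011, and adjusted p = 0.958 with an estimated correlation). Fabp1, the liver-type fatty acid binding protein, stood at 2674 ± 160 FPKM in Ctrl (SD, n = 3) and 1219 ± 383 FPKM in cKO (SD, n = 4), with a limma adjusted p of 0.473. Acot2, a mitochondrial thioesterase, stood at 2.37 ± 0.443 and 1.37 ± 0.148 FPKM. Acadvl, which starts the oxidation of very long chain fatty acids, stood at 94.9 ± 13.2 and 72.3 ± 4.43 FPKM, and the lipid droplet protein gene Plin2 at 30.0 ± 3.55 and 25.7 ± 2.16 FPKM. No member passed in limma, over all genes or when adjusted over the list alone (0 and 0). The mean of the list differed by -0.26 on the log2 scale (SE 0.11, exact 2-sided permutation p = 0.114). Relative to the Ctrl mean it lay at -0.44 and -0.41 in cKO replicates 1 and 2, and at -0.015 and -0.16 in cKO replicates 3 and 4. The Ctrl libraries lay between -0.10 and 0.057. Without cKO replicate 1 the adjusted p of the list was 0.218 and its median was -0.088, and after quantile normalization the adjusted p was 0.091 and the median -0.078. The median was also smaller without Ctrl replicate 2 (-0.092) or cKO replicate 2 (-0.11), with TPM (-0.082) and with the sum that left out abundant genes (-0.074).

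MHC class I presentation genes were lower in 11 of 13 members, with a median log2 difference of -0.36 (camera adjusted p = 0.00029, and adjusted p = 0.958 with an estimated correlation). In limma, 0 members passed over all genes and 1, H2-T23, passed when adjusted over the list alone. H2-Q4 stood at 55.7 ± 7.14 FPKM in Ctrl (SD, n = 3) and 42.9 ± 3.71 FPKM in cKO (SD, n = 4). Tap2, a subunit of the transporter that carries peptides into the endoplasmic reticulum, stood at 44.6 ± 5.75 and 32.1 ± 7.89 FPKM, and the immunoproteasome subunit Psmb8 at 163 ± 23.4 and 120 ± 25.3 FPKM. The mean of the list was 0.35 lower in cKO (SE 0.15), and all 3 Ctrl libraries lay above all 4 cKO libraries (exact 2-sided permutation p = 0.0571, the smallest possible), by a narrow margin between Ctrl replicate 2 at -0.132 and cKO replicate 4 at -0.152. This margin rests on H2-T23, at 327 FPKM in Ctrl replicate 2 and 182 FPKM in cKO replicate 4. Without that gene the mean of the list would not separate the groups. Immune cell markers moved with the class I list in part: relative to the Ctrl mean, Ctrl replicate 1 and cKO replicates 1 and 2 stood at 0.22, -0.39 and -0.59 for class I, at 0.62, -0.99 and -0.64 for T cells and ILC, and at 0.30, -0.28 and -0.80 for MHC class II presentation (camera adjusted p = 0.071). In cKO replicates 3 and 4, class I stood at -0.26 and -0.15, T cells and ILC at -0.015 and 0.16, and MHC class II at -0.24 and 0.064. After removal of the GC trend the median was -0.22. Gm8810, a pseudogene in the same region as H2-T23 that was chosen after its values were seen, was listed at 0 in the 3 Ctrl libraries and between 0.441 and 1.86 FPKM in the 4 cKO libraries (limma adjusted p = 0.452). Class I genes are similar in sequence, and their single values depend on how reads were divided among them.

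**Figure D2:**
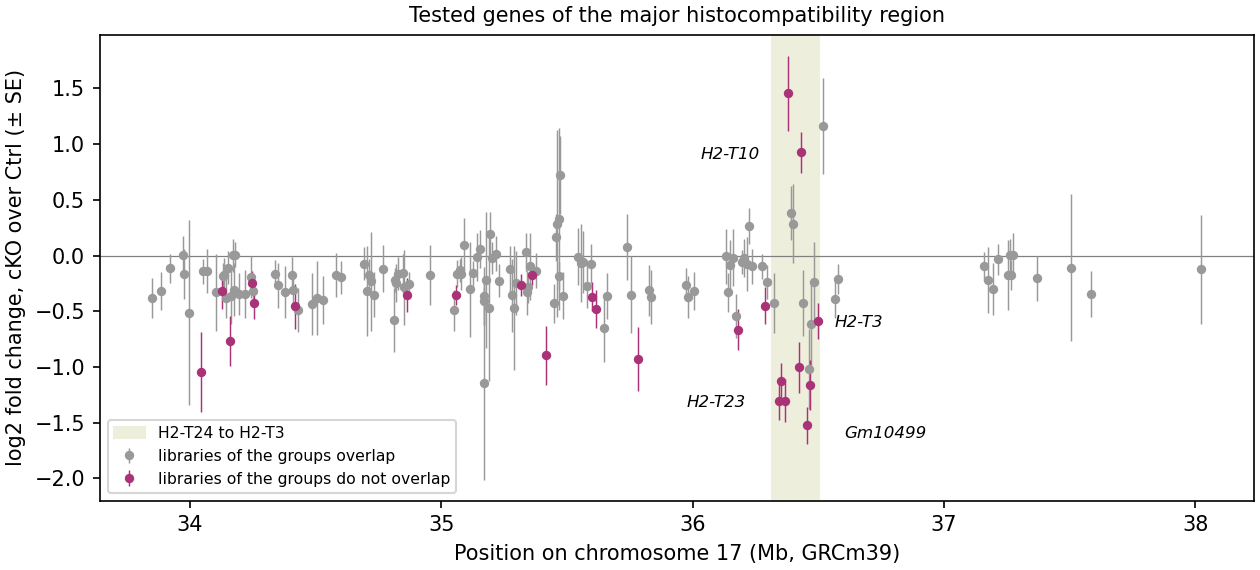
Log2 fold change, cKO over Ctrl, of tested genes along chromosome 17 in Mb of GRCm39, with error bars of 1 SE, and genes whose libraries do not overlap between the groups in purple. In the shaded stretch from H2-T24 to H2-T3, 12 of 16 tested genes were lower in cKO, with H2-T23 at -1.30 and Gm10499 at -1.53, and among the 4 higher ones the libraries of the groups did not overlap for H2-T10, at 0.93, and Gm8810, listed at 0 in Ctrl.

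Immunoglobulin genes, which mark plasma cells and B cells rather than epithelium, were higher in cKO in 23 of 27 members, with a median log2 difference of 0.57 (camera adjusted p = 0.00044, and adjusted p = 0.958 with an estimated correlation). Most were near the lower limit, with a median of 0.820 FPKM, and with a mean of at least 1 FPKM required the adjusted p was 0.053 and the median 0.41. The median depended on how low values were treated, at 1.01 with a pseudocount of 0.1, 0.36 with a pseudocount of 1 and with array weights, 0.26 with no filter and 1.18 with voom, and was 0.91 without Ctrl replicate 2. In limma, 0 members passed over all genes and 2, Ighg2b and Ighv1-80, passed when adjusted over the list alone. Ighv1-80 stood at 0.0584 ± 0.101 FPKM in Ctrl (SD, n = 3) and 0.911 ± 0.346 FPKM in cKO (SD, n = 4), Ighv6-3 at 0.230 ± 0.398 and 1.06 ± 0.574 FPKM, and Iglv1 at 0.211 ± 0.184 and 1.52 ± 1.21 FPKM. The list was highest in cKO replicate 4, at 1.26 above the Ctrl mean, and lay at -0.041 in cKO replicate 1. The list of plasma cell markers, which holds 14 tested genes, had an adjusted p of 0.349.

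Markers of T cells and innate lymphoid cells (ILC), cells that lie between and below epithelial cells, were lower in 22 of 24 members, with a median log2 difference of -0.40 (camera adjusted p = 0.011, and adjusted p = 0.958 with an estimated correlation). In limma, 0 members passed over all genes and 0 when adjusted over the list alone. Trbc1, a constant region of the T cell receptor, stood at 18.9 ± 7.87 FPKM in Ctrl (SD, n = 3) and 10.4 ± 5.87 FPKM in cKO (SD, n = 4), and Cd247, a chain of the CD3 complex, at 0.896 ± 0.458 and 0.464 ± 0.155 FPKM. The integrin gene Itgae stood at 16.9 ± 7.39 and 11.49 ± 3.74 FPKM and the granzyme gene Gzma at 428 ± 234 and 291 ± 117 FPKM. The call was lost without Ctrl replicate 1 (adjusted p = 0.812, median -0.11), without cKO replicate 1 (adjusted p = 0.451, median -0.25) and without cKO replicate 2 (adjusted p = 0.061, median -0.35). Leaving out any of the other 4 libraries made the median larger, between -0.50 without cKO replicate 4 and -0.60 without Ctrl replicate 2.

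**Figure D3:**
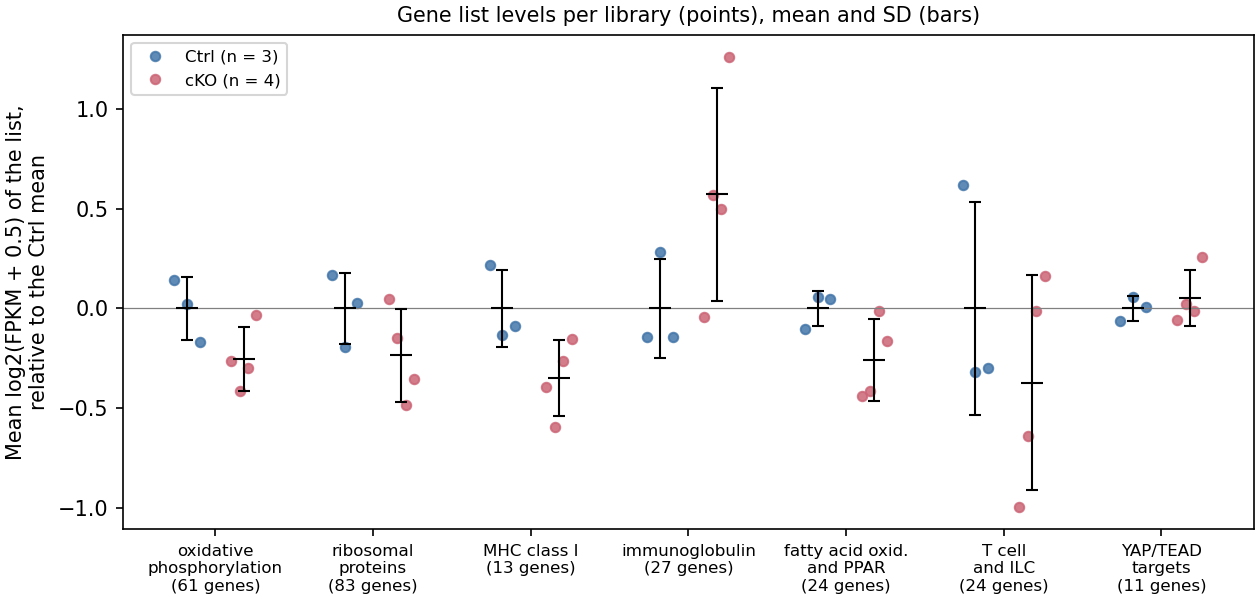
Mean log2(FPKM + 0.5) of each gene list in each library, relative to the mean of the 3 Ctrl libraries, for the 6 lists that passed in camera and the YAP/TEAD targets, with points for libraries and bars for the mean and SD. Only in the class I list did the 4 cKO libraries all lie below the 3 Ctrl libraries, by a narrow margin that rests on H2-T23. The T cell and ILC list of Ctrl replicate 1 stood at 0.62.

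The title of the series led to the question of whether transcripts driven by YAP and its TEAD partners differed between the genotypes. Of 11 targets that could be tested, 8 were higher and 3 lower in cKO, with a median log2 difference of 0.087, and the list did not pass (camera adjusted p = 0.835). The targets Gadd45a, at 29.6 ± 5.32 FPKM in Ctrl (SD, n = 3) and 20.9 ± 2.55 FPKM in cKO (SD, n = 4), and Nuak2, at 27.7 ± 4.67 and 24.2 ± 6.20 FPKM, were abundant, whereas Ccn1 stood at 0.473 ± 0.395 and 0.665 ± 0.2996 FPKM and Myof at 0.615 ± 0.175 and 0.972 ± 0.374 FPKM. In limma, 0 of the 11 passed over all genes and 0 when adjusted over the list alone. The mean of the list differed by 0.053 on the log2 scale (SE 0.079, exact 2-sided permutation p = 0.743), and the sign of the small median was not stable, at -0.023 without cKO replicate 4. Hippo pathway components (adjusted p = 0.168), regenerative and fetal-like epithelial genes (0.808), Wnt targets (0.775), proliferation genes (0.480) and intestinal stem cell genes (0.816) did not pass in camera either, and the only member of the first of these lists to pass in limma was Stk24 itself. Proliferation genes passed with array weights (0.00051), with the replicate number as a block (0.028) and without cKO replicate 3 (0.00038). Stem cell genes passed with array weights (0.043), with the block (0.020) and without cKO replicate 4 (0.032). With all libraries and an estimated correlation the lists had an adjusted p of 0.958 and an adjusted p of 0.969.

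Epithelial transcripts were abundant in the 7 libraries beside those of lymphoid cells, and their regional markers were those of small intestine rather than of large bowel. Epcam ranged from 689 to 987 FPKM over the 7 libraries and Krt20 from 738 to 1569 FPKM, whereas the collagen gene Col1a1 did not exceed 0.333 FPKM. Of lymphoid genes, Gzma ranged from 182 to 696 FPKM, Cd3e from 10.5 to 43.2 FPKM and Igkc from 10.8 to 111 FPKM. The apolipoprotein genes Apoa1, from 7254 to 14465 FPKM, and Apoa4, from 4553 to 10415 FPKM, were among the most abundant transcripts, and sucrase-isomaltase (Sis) ranged from 413 to 823 FPKM and lactase (Lct) from 280 to 523 FPKM. The Paneth cell defensin Defa24 ranged from 2033 to 16415 FPKM, and Gata4, a transcription factor of the proximal small intestine, from 39.9 to 53.8 FPKM. Of genes of the colon, Car1 did not exceed 0.0705 FPKM and Aqp8 did not exceed 1.56 FPKM, and Hoxd13 was listed at 0 in all 7 libraries. The list of small intestinal markers did not pass in camera between the genotypes (adjusted p = 0.459), nor did that of the distal colon (0.131, but 0.047 without cKO replicate 2, and adjusted p = 0.958 with an estimated correlation and all libraries).

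**Figure D4:**
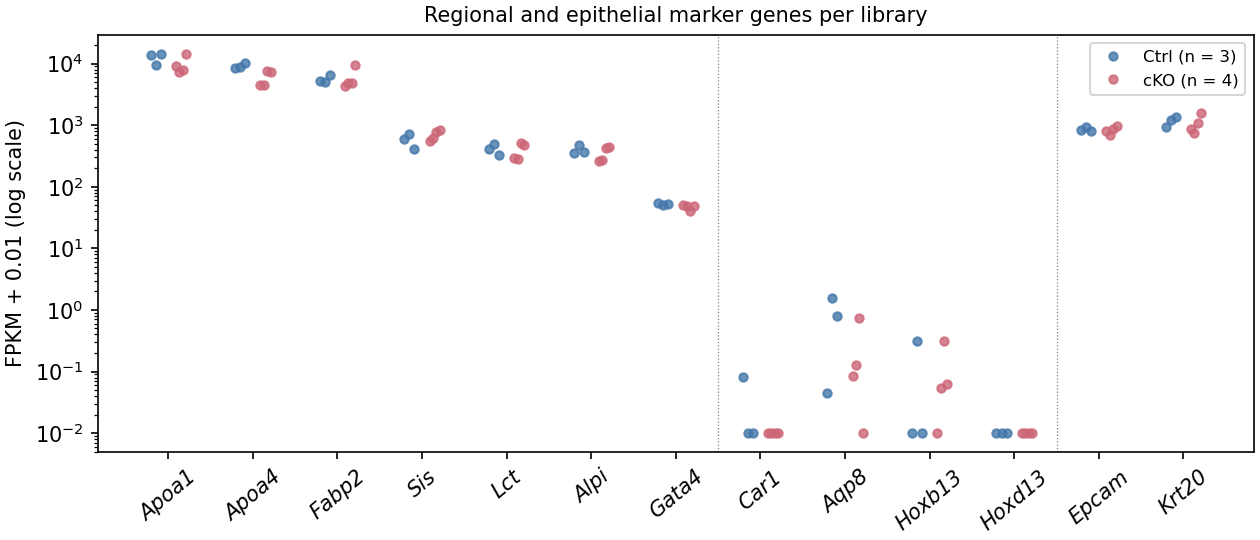
FPKM + 0.01 of marker genes in each of the 3 Ctrl and 4 cKO libraries on a log axis, with genes of the small intestine on the left, of the colon in the middle and of epithelium as a whole on the right. Apoa1 lay at or above 7254 FPKM in every library, and Aqp8 at or below 1.56 FPKM.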

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

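No test in this part was chosen after its result was seen. In the group of 4 cKO libraries, 62 measurements (each named gene and the mean of each list that passed, with the YAP/TEAD list) were searched for a library far from the other 3. For Rps27a, a ribosomal protein gene, cKO replicate 1 stood at 125 FPKM, whereas the other 3 cKO libraries lay between 84.5 and 91.2 FPKM. The gap made up 0.833 of the range of the group, above the 95% critical value of Dixon's test for 4 libraries. Chance gives 3.1 such results among 62, so 1 is fewer than chance alone would give. The 3 Ctrl libraries were too few for the same search.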

How the results depend on the processing

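FPKM per recovered read, voom, protein-coding genes only and the removal of length and GC trends were chosen after seeing the data, all others before. Stk24 kept its direction and its call in limma under 23 of 24 alternatives, with log2 differences between -2.48 and -2.37 and adjusted p between 0.0013 and 0.0093 when 1 library was left out. The count of 4 genes was less stable. It was 1 with a pseudocount of 0.1, with no filter, with a mean of at least 1 FPKM and after removal of the length trend, 2 with the sum that left out immunoglobulin, mitochondrial and the 20 most abundant genes, with voom on recovered reads, with protein-coding genes only and after removal of the GC trend, and between 1 and 7 when 1 library was left out. Gm10499 passed under 8, Gm5425 under 6 and Mir7052 under 11 of the 24. The count of 6 lists was 13 with array weights, 11 with FPKM per recovered read, 10 with camera on ranks, and between 5 and 14 when 1 library was left out. It was 0 with camera and an estimated correlation and 0 with the directional p of fry, and neither gave any list an unadjusted p under 0.05 (0 and 0). The p of fry for change in either direction passed for 3 lists, Hippo components (adjusted p = 1.98e-07) and STRIPAK partners (3.24e-07), which both hold Stk24, and mitochondrial quality control (0.042); of the 6 called lists, oxidative phosphorylation (0.014) and class I (0.0050) had an unadjusted p under 0.05 there. The lists of oxidative phosphorylation and class I genes passed under all 24 alternatives that kept the preset correlation. The median of the YAP/TEAD targets, never past the threshold, went with a camera direction opposite to that of the reported value at 0.017 with a mean of at least 1 FPKM, -0.017 with array weights and 0.0041 after removal of the length trend, and ranged from -0.023 to 0.167 when 1 library was left out. Yap1, also never past it, turned to 0.056 with TPM, 0.0034 with quantile normalization and 0.064 with the sum that left out abundant genes, and lay between -0.106 and 0.0096 without 1 library. Stk25 lay between -0.36 and 0.028 and Pgam5 between -0.020 and 0.184 without 1 library. The cause of these shifts was not tested. The immunoglobulin list had no value with protein-coding genes only, since its members carry other biotypes. Tests on counts (edgeR and DESeq2) had been planned in case whole reads could be recovered; the reads were recovered, but these tests were not run, and voom is the only test here on reads. Xist as a covariate was not run, since the libraries differed by 1.41 on its log2 scale, below the limit of 4. The depth of 14659708 to 19659622 reads limits statements on genes 1 kb long below 0.216 FPKM.

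With the replicate number as a block, limma called 0 genes (1052 at an unadjusted p under 0.05), Stk24 stood at -2.44 with an adjusted p of 0.137, 15 lists passed and the YAP/TEAD median was -0.023. This fit also takes cKO replicate 4, which has no Ctrl library of its number, out of the comparison, and leaving out that library alone gave the same log2 differences, 1 gene and 14 lists. The values gave no clear sign that the numbers pair the libraries, though so few libraries cannot exclude it. Deviations of libraries with the same number correlated at 0.115, -0.087 and -0.129. While cKO replicate 1 correlated best with the Ctrl library of its own number, cKO replicates 2 and 3 correlated best with Ctrl libraries of another number.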

Other observations

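Tests of a chromosome 17 haplotype, of class I expression as a whole, of admixed tissue and of mixed-up libraries were chosen after the values they bear on had been seen; those of gene length, GC content and shared reads were added after the data were seen, with predictions written before their results, except that the test of shared reads was held to the spread between libraries only after its result was seen.

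Besides the lists described for the genotypes, the libraries of cKO differed among themselves in 2 abundant Paneth cell transcripts, a difference that was not tested. Lyz1, the lysozyme of Paneth cells, stood at 5049 and 4577 FPKM in cKO replicates 1 and 2 and at 1207 and 1008 FPKM in replicates 3 and 4, and Defa24 stood at 9268 and 8484 FPKM against 2125 and 2033 FPKM. For Lyz1 the Ctrl libraries lay between, at 2649 ± 383 FPKM (SD, n = 3), and for Defa24 they spread from 4550 to 16415 FPKM. The list of deep crypt secretory and Paneth-like genes had a camera adjusted p of 0.480 between the genotypes, and 0.023 without cKO replicate 2, with an adjusted p of 0.958 with an estimated correlation and all libraries. Xist ranged from 17.97 to 48.5 FPKM and the Y-linked gene Ddx3y was listed at 0 in all 7 libraries. H2-Ea, a class II gene that strains of the b haplotype do not transcribe, was listed at 0 in 6 libraries and at 0.0569 FPKM in the other, although H2-Aa ranged from 193 to 472 FPKM and the mice are labelled as BALB/C.

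Chance cannot be excluded for the number of called genes. Of the 35 splits of the 7 libraries into 3 and 4, the real one included, 3 gave at least 4 genes in limma, and the highest other split gave 12. That split set cKO replicates 1 and 2 with Ctrl replicate 1, which points to a structure of the samples beside the genotype, although it was picked as the highest of 34 other splits and the structure itself was not tested. For lists, all 35 splits gave at least 6 in camera with the preset correlation, the real split gave 6 and the highest other split gave 22, so the number of lists carries no evidence of a genotype effect.

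The lower transcripts of the H2-T region, from 36314363 to 36501043 on chromosome 17, form the pattern most open to explanation. Reads shared between near-identical class I genes would leave their sum in place, provided that each such read was counted for one of these genes. The counting program is not given, so a fall of the sum does not by itself speak against shared reads. The sum changed by -0.376 on the log2 scale in cKO, without overlap of the groups as had been set beforehand to count against shared reads. However, cKO replicate 4, at 94.2 scaled kiloreads, came close to Ctrl replicate 3, at 94.7. The fall lay mainly in cKO replicates 1 and 2, at 64.1 and 59.3. Outside the region the mean was no higher in cKO (76.0 in Ctrl, 64.8 in cKO), but the libraries overlapped, with Ctrl at 84.2, 70.9 and 72.9 and cKO at 54.0, 49.9, 74.5 and 80.5, so that the spread between cKO libraries keeps shared reads open and they cannot be told apart from a real difference. A lower level of class I genes as a whole is a candidate explanation. By summed reads the region itself was at -0.99, while class I genes outside it went from 76.0 to 64.8 scaled kiloreads. By single genes, the 12 members of the class I list outside the region had a median of -0.35, against -0.60 for the 16 tested genes of the region. However, members such as Psmb8, Tap2 and H2-Q4 also lie on chromosome 17, where a haplotype difference could shift them too. The median of -0.35 therefore cannot assign any part of the pattern to lower class I expression or to a haplotype. A strain haplotype that differs between the groups is another candidate: outside class I genes, 3.45% of chromosome 17 genes had an unadjusted p under 0.01 against 1.69% elsewhere (but 3.14% on X and 2.98% on chromosome 10), which 10000 circular shifts of the gene order left undecided (permutation p = 0.0555), with Gm8810 higher and most of its neighbours lower in cKO, and an effect of the knockout itself stays open too.

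Lower oxidative phosphorylation transcripts go with the short length of these genes. After each library's trend with GC content was removed, the median was -0.17, against -0.19 before (camera adjusted p = 7.94e-09 at the preset correlation). The size that was left argues against a GC trend as the main source of this median. The p adds little, since all 35 splits of the libraries gave at least 6 lists in camera at that correlation. With an estimated correlation and no trend removed, the list did not pass (camera adjusted p = 0.958). Removal of the trend with gene length took the median from -0.19 to -0.055, or 28.4% of its size, with an adjusted p of 0.040, so that a length trend may account for most of the difference but the remainder and the trend cannot be told apart from a change in these genes with 7 libraries. A difference between the genotypes stays among the open explanations.

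Small-intestinal transcripts in libraries labelled as large bowel are the third pattern. Small-intestinal tissue admixed to colon would keep the abundant colon genes, but Car1 and Aqp8 did not exceed 1.56 FPKM. Single mixed-up libraries are argued against because in all 7 the median of the small intestine list, which ranged from 577 to 960 FPKM, was over 10 times that of the distal colon list, at most 0.448 FPKM. These values argue against large bowel as the main tissue of any of the 7 libraries. Gata4 also stood between 39.9 and 53.8 FPKM, and Hoxa13 and Hoxd13 were listed at 0 in all of them. What stays open is how the label arose. The epithelium may have been taken from small intestine in place of large bowel, or the label may be broad, and no test here separates these. For this pattern no biological explanation was tested, since the design names only genotype.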
